A study of Homo sapiens with 12 samples.

How the data were processed

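RNA was extracted from cultured HepG2 cells at 120 h after transfection with 1 of 4 small interfering RNAs, 3 samples per group and 12 in all, and biotin-labelled cDNA was hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are log2 intensities of 53617 probe sets, made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects the background, makes the intensity distributions of the arrays equal and summarises the probes of each probe set, so a change shared by most genes would be removed and changes near the floor of the array are compressed. Library files, annotation build and the level of the probe sets are not given in the sources used here, and raw scanner intensities were not used here. The scale (log2) was inferred from the range and the near-equal distributions of the deposited columns, and the genes were not centred. The medians over all probe sets were 4.75, 4.72 and 4.71 for siCtrl replicates 1 to 3, 4.73, 4.74 and 4.72 for si-WT, 4.78, 4.75 and 4.74 for si-mut, and 4.74, 4.79 and 4.74 for si-both. Groups and replicate numbers were taken from the sample titles.

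Probe sets were named through an annotation table of the platform. Of the 53617 probe sets 16098 had 1 gene symbol, 0 had several and 37519 were not listed and stayed unnamed. All 16098 gene identifiers matched the reference gene table, and 0 symbols were updated. For 779 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 14884 genes. No filter on dim genes was applied. The targeted gene and a further gene planned for the text are among the genes not analysed here, so the labels could not be checked against the targeted gene.

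The tests were fixed before the data were examined. The log2 values of all 12 arrays were fitted with 4 group means in limma 3.58.1 (R 4.3.3, lmFit and eBayes), with 8 residual degrees of freedom and a median of 13.3 with the prior. Tests were two-sided with Benjamini-Hochberg adjustment within each comparison, and a gene was called at an adjusted p under 0.05. The 7 contrasts were each knockdown against siCtrl, the knockdowns against each other, and the departure from additivity (si-both minus si-WT minus si-mut plus siCtrl). Changes are log2 differences of group means with the standard error of the fit, and fold changes were computed from them. Overlaps of comparisons that share the control arrays were set beside 100 simulations of unchanged groups with the same controls.

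The 27 gene lists were written from general knowledge, also beforehand, and 4 of them hold markers of other cell types. They were tested with camera at a preset correlation of 0.01, adjusted over all lists within a comparison, with camera at an estimated correlation and fry beside it. Named genes followed a rule fixed in advance. It took the 8 highest and 8 lowest log2 changes among called genes whose 3 arrays of each group did not overlap, for the knockdowns against siCtrl and for si-mut against si-WT, leaving out open reading frame names and small or uncharacterised RNA symbols. It added 4 in each direction for si-both against each single knockdown and, with no condition on overlap, for additivity, the 10 genes with the largest opposite changes after si-WT and si-mut, and up to 4 members of each list that was called or had at least 3 called members, and up to 2 members of any other list. Groups of 3 arrays do not overlap by chance in 10% of genes.

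The steps were tested on simulated data with the spread of the real arrays, in which genes of si-WT against siCtrl were changed by known amounts among 14884 genes. The test recovered 86.6% of 67 genes changed by a log2 of 0.5, 100% of 67 changed by 1 and 100% of 66 changed by 2, with 14 false calls among 205. A list shifted on purpose was called, and 0 of the others were. Each simulated gene had the same spread in every group and no replicate effect. In the real data the array weights were 0.635 to 0.707 for si-both and 1.02 to 1.84 for siCtrl, so recovery there may differ. The simulated genes were drawn independently, so this does not show how the list test behaves where members are correlated. In the real data the estimated correlation was 0.652 for mitosis and 0.702 for DNA replication genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

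The titles give the same replicate numbers in each group. Whether numbers pair the arrays was checked by the correlation of deviations from the group means. For si-both against si-WT all 3 pairs were above 0.1 (0.115, 0.155 and 0.134), so by the rule fixed for this check the numbers pair these arrays, from the data and not from the labels. Alternatives tried were renewed quantile normalization, median centring, a filter that left out genes under the 40th percentile of the mean, the mean of a gene's probe sets, a trended and a robust prior, only the groups compared, the replicate number as a block, array weights, a 1.5-fold limit, an adjusted p under 0.01, camera with an estimated correlation, fry, each array left out in turn and, chosen after seeing the data, the first arrays of si-mut and si-both left out together.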

Results

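Gene expression was measured on 12 Affymetrix arrays in HepG2, an established cell line from a human liver tumour that keeps many features of hepatocytes. In this line 1 allele of the β-catenin gene has lost exon 3, which encodes the sites through which β-catenin is marked for degradation, so the cells hold a truncated protein beside the full-length protein. β-catenin acts both at cell junctions and as the transcriptional effector of Wnt signalling. The cells received 1 of 4 small interfering RNAs and were sampled at 120 h: a control RNA (siCtrl), an RNA against the full-length form (si-WT), an RNA against the truncated form (si-mut), or an RNA against both forms (si-both). Each group held 3 arrays. The design asks what each form of β-catenin contributes to gene expression in these cells. The values were log2 intensities, and the number of arrays limits the precision. The labels call the samples triplicates without saying that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

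The tests covered 14884 genes. The probe sets of the targeted gene itself were not analysed here, so the knockdown could not be checked from these values and the groups rest on the labels. Replicate arrays correlated at r = 0.994 to 0.997 across genes, and 0 pairs of arrays held identical values. The first principal component held 56.8% of the variance and placed the si-WT arrays (-28.8 to -27.5) and the siCtrl arrays (-19.2 to -18.8) on the opposite side from the si-mut arrays (15.7 to 17.2) and the si-both arrays (26.7 to 33.7). The median log2 change over all genes was 0.005, 0.011 and -0.006 after si-WT, si-mut and si-both. Levels near the medians of all probe sets (4.71 to 4.79) lie close to the array floor, where changes are compressed, so changes from or to such levels are given on the log2 scale and their size is uncertain. Across the 4 groups, 6749 genes differed by limma's moderated F test at an adjusted p under 0.05.

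After knockdown of the full-length form, the glutathione transferases GSTA2 and GSTA1, which detoxify electrophiles, fell by 2.57 ± 0.23 and 2.26 ± 0.17 on the log2 scale against siCtrl, with GSTA2 at a level of 4.93 after si-WT, close to the array floor (SE, n = 3 arrays per group, limma adjusted p = 1.51e-05 and 7.67e-06). The homeobox factor MIXL1 fell 5.75-fold, the liver carboxylesterase CES1 fell 3.09-fold and the plasma zymogen gene PLG (plasminogen) fell by 1.66 on the log2 scale. ANKRD1, a target of the co-activator YAP, rose 4.05-fold, FRMD5 rose 3.73-fold, the receptor tyrosine kinase AXL rose 3.66-fold, the cell-surface protein FLRT2 rose 3.41-fold and the adhesion molecule ESAM rose 3.09-fold. The long non-coding RNA UCA1 rose by 1.59 on the log2 scale and CSGALNACT2, an enzyme of chondroitin sulfate synthesis, rose 2.78-fold. PLGLA, SNAP25-AS1 and ASAH2 were the other genes among the 8 largest decreases (log2 changes -1.80, -1.57 and -1.54), and GPR83 completed the 8 largest increases at 1.47. GSTA1 and GSTA2 are near-identical copies, as are PLG and PLGLA, so the values within each pair may share signal and are uncertain for the single gene. In all, 1513 genes passed an adjusted p under 0.05, 774 higher and 739 lower, and 79 of them changed at least 2-fold. The count rests on few arrays: it was 950 without siCtrl replicate 2, 917 without si-WT replicate 2 and 957 without si-WT replicate 3.

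Among the gene lists fixed beforehand, secreted plasma proteins were lower after si-WT. Of 26 measured members 13 fell and 1 rose, or 14 and 1 adjusted over the list alone (camera adjusted p = 2.06e-07 with a preset correlation, adjusted p = 0.278 with an estimated correlation). The haptoglobin gene HP fell by 1.21 on the log2 scale, the inter-alpha-trypsin inhibitor ITIH3 by 0.73, and the fibrinogen chains FGG and FGA by 0.67 and 0.63, while HPX (haemopexin) rose by 0.60. Of 17 genes of cholesterol synthesis 7 fell and 0 rose, or 10 and 0 adjusted over the list alone, with ACAT2 at -0.56 and SQLE at -0.30 (adjusted p = 5.42e-06, and adjusted p = 0.296 with an estimated correlation). Of 10 periportal liver genes 3 fell and 0 rose, with the same counts adjusted over the list alone: AGXT by 1.37, the histidine-degrading enzyme HAL by 0.87 and the urea cycle enzyme ASS1 by 0.59 (adjusted p = 0.000589, and adjusted p = 0.0538 with an estimated correlation). Of 15 genes of glycolysis and hypoxia 4 fell and 0 rose, or 5 and 0 adjusted over the list alone, with BNIP3 at -0.47 (adjusted p = 0.000254, and adjusted p = 0.278 with an estimated correlation). Of 10 genes of fatty acid oxidation 5 fell and 0 rose, or 5 and 1 adjusted over the list alone, with the nuclear receptor PPARA at -0.60 and ECI2 at -0.47 (adjusted p = 0.0241, and adjusted p = 0.496 with an estimated correlation). The fatty acid oxidation call ended without si-WT replicate 3 (adjusted p = 0.0501) and without dim genes (adjusted p = 0.0664). Of the 30 drug metabolism genes listed only 3 were measured, and GSTA1 and GSTA2 were the 2 that fell, before and after adjustment over the list alone (adjusted p = 0.00154, and adjusted p = 0.165 with an estimated correlation).

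The lists called in the other direction after si-WT were p53 targets and targets of YAP and TEAD. Of 16 p53 targets 9 rose and 1 fell, or 12 and 1 adjusted over the list alone (adjusted p = 1.21e-06, and adjusted p = 0.0538 with an estimated correlation). GDF15, a secreted stress factor, rose by 0.83, TP53INP1 by 0.60 and TIGAR, a regulator of glycolysis, by 0.46. Of 13 YAP and TEAD targets 4 rose and 0 fell, or 6 and 0 adjusted over the list alone, led by ANKRD1 and AXL (adjusted p = 0.000175, and adjusted p = 0.145 with an estimated correlation). The list of Wnt targets was not called after si-WT: 1 of 18 members rose, the cyclin CCND1 by 0.43, and 2 fell, APCDD1 by 0.62 and DKK4 by 0.60, with 2 and 2 adjusted over the list alone (adjusted p = 0.603). The R-spondin receptor LGR5 stood at 11.41 ± 0.08 (SD, n = 3) after siCtrl and 11.37 ± 0.03 after si-WT. The Wnt feedback genes AXIN2, NKD1 and NOTUM had log2 changes of 0.43 ± 0.26, 0.46 ± 0.31 and 0.57 ± 0.23 (SE) that did not pass the test with all 4 groups in the fit (limma adjusted p = 0.405, 0.469 and 0.168). They passed with only the groups compared in the fit (adjusted p = 0.01, 0.00326 and 0.00159). They also passed with all 4 groups when the first arrays of si-mut and si-both, which stood apart on these genes, were left out (adjusted p = 0.0215, 0.00966 and 0.000537, an alternative chosen after seeing the data). NOTUM passed without si-both replicate 1 alone (adjusted p = 0.00151) and with array weights (0.0489). Over all alternatives their adjusted p ranged from 0.01 to 0.609, 0.00326 to 0.618 and 0.000537 to 0.318. Mitosis, DNA replication and ribosome biogenesis genes were not called after si-WT (adjusted p = 0.15, 0.406 and 0.505).

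Knockdown of the truncated form lowered the Wnt target genes. LGR5 fell 22.5-fold against siCtrl, NKD1 11.5-fold, AXIN2 11.1-fold, the secreted Wnt inhibitor NOTUM 8.22-fold and the transcription factor MYC 5.44-fold (log2 changes -4.49 ± 0.43, -3.52 ± 0.31, -3.47 ± 0.26, -3.04 ± 0.23 and -2.44 ± 0.11, SE, n = 3 arrays per group, limma adjusted p = 5.14e-06, 2.69e-06, 7.27e-07, 7.97e-07 and 1.04e-08). Of the 18 measured Wnt targets 13 fell and 1 rose, with the same counts adjusted over the list alone and a median log2 change of -1.71 (camera adjusted p = 4.09e-11, and adjusted p = 0.104 with an estimated correlation). The ubiquitin ligases ZNRF3 and RNF43, which remove Wnt receptors from the membrane, fell 4.26-fold and 3.99-fold. The member that rose was the Wnt inhibitor DKK4, by 1.78. The first si-mut array stood apart from the others of its group on some of these genes: its LGR5 level was 8.17 beside 6.57 and 6.02, and its NKD1 level was 7.71 beside 6.53 and 6.43. Its levels of RNF43 (7.09 beside 7.07 and 7.08) and MYC (6.99 beside 6.91 and 6.81) were close to the others. Without si-mut replicate 1 the log2 change of LGR5 was -5.12. Outside the list, CHST15, PGC and CEMIP fell 8.85-fold, 7.98-fold and 6.69-fold.

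**Figure D1:**
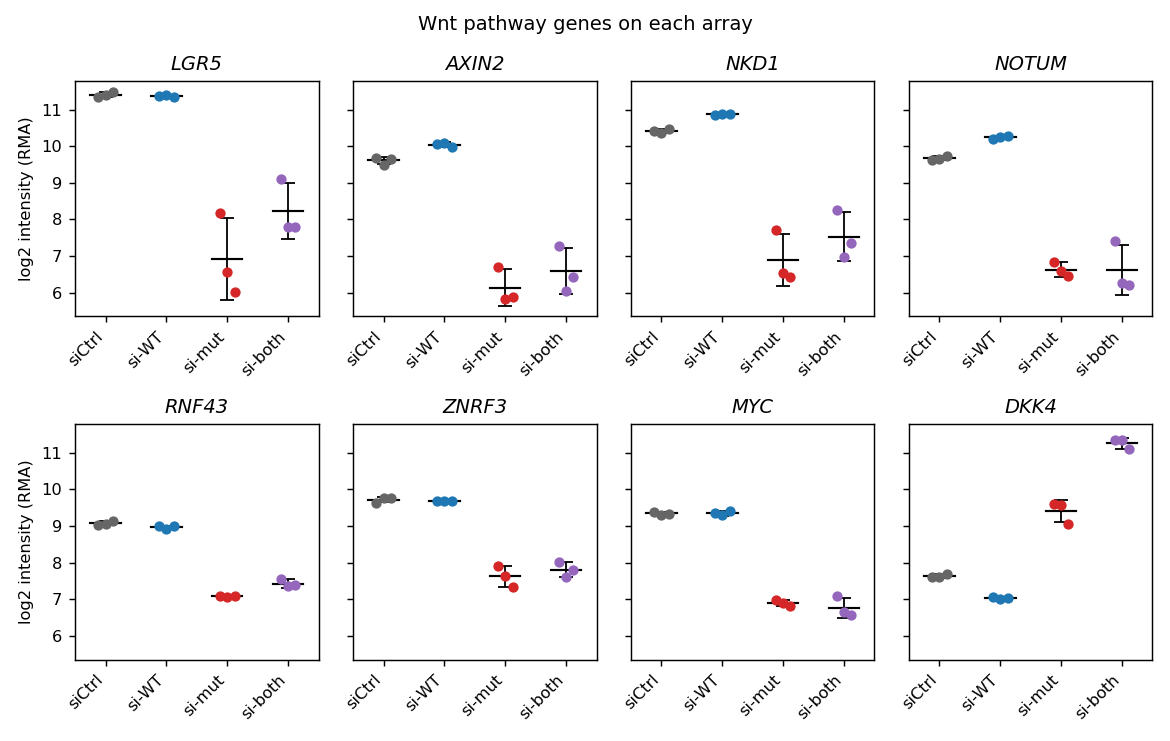
Log2 intensity (RMA, vertical axis) of 8 genes of the Wnt pathway in the 4 groups, where points are single arrays in replicate order and bars are the mean and SD of 3 arrays. LGR5 lies near 11.4 in siCtrl and si-WT and at 6.92 and 8.23 on average in si-mut and si-both, while DKK4 is higher in si-mut and si-both.

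The genes of secreted plasma proteins rose after si-mut. Of 26 members 23 rose and 0 fell, or 24 and 0 adjusted over the list alone, with HPX at 2.20 and ITIH1 at 2.01 (adjusted p = 2.24e-19, and adjusted p = 0.0714 with an estimated correlation). Among single genes, the plasma serine protease HABP2, HAL, the kininogen gene KNG1 and FETUB (fetuin B) rose by 4.65 ± 0.19, 4.32 ± 0.19, 3.88 ± 0.11 and 3.34 ± 0.12 on the log2 scale, for KNG1 and FETUB 14.7-fold and 10.1-fold (SE, n = 3 arrays per group, limma adjusted p = 5.66e-09, 9.7e-09, 1.27e-10 and 1.41e-09). The peptide hormone gene GAST rose by 3.58 on the log2 scale, the transcription factor SNAI2 8.46-fold and PGLYRP2 7.71-fold. The pantetheinase VNN1 rose by 3.48 on the log2 scale from a siCtrl level of 4.18, near the array floor, where changes are compressed. With the mean of its probe sets KNG1 rose by 2.02 on the log2 scale. Of 10 periportal genes 5 rose and 0 fell, also over the list alone, with PCK1, an enzyme of gluconeogenesis, at 1.57 (adjusted p = 0.00402, and adjusted p = 0.0714 with an estimated correlation). Of 9 hepatocyte transcription factors 6 rose and 1 fell, also over the list alone, with ONECUT1 at 1.80 and GATA6 at -0.85 (adjusted p = 0.00826, and adjusted p = 0.0895 with an estimated correlation). Of 17 genes on the cholesterol synthesis list 16 rose and 0 fell, also over the list alone (adjusted p = 2.09e-11, and adjusted p = 0.1 with an estimated correlation). Among them STARD4, which transfers sterols, rose by 1.09 and MVK, an enzyme of the synthesis, by 0.90. Lipogenesis genes rose in 10 of 18 cases and fell in 2, or 12 and 2 adjusted over the list alone, with ACSS2 at 1.30 (adjusted p = 0.000205, and adjusted p = 0.266 with an estimated correlation). Fatty acid oxidation genes rose in 4 of 10 cases and fell in 1, or 7 and 1 adjusted over the list alone, with the carnitine transferase CPT1A at 1.49 (adjusted p = 0.00239, and adjusted p = 0.185 with an estimated correlation). Of 14 acute phase genes 4 rose and 1 fell, also over the list alone, with LBP at 1.57 and the iron hormone gene HAMP at -0.69 (adjusted p = 0.0292, and adjusted p = 0.185 with an estimated correlation). Only 4 of the 20 listed bile acid genes were measured, and 3 rose, BAAT, SLC51A and SLC51B, with none falling and the same counts over the list alone (adjusted p = 0.000401, and adjusted p = 0.0714 with an estimated correlation). GSTA1 and GSTA2 were again the 2 of 3 measured drug metabolism genes that changed, now upward, also over the list alone (adjusted p = 0.00479, and adjusted p = 0.142 with an estimated correlation).

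Proliferation genes were lower after si-mut. Of 19 mitosis genes 19 fell, also over the list alone, by a median of 0.57 on the log2 scale, with BUB1 at -0.79 and CDK1 at -0.70 (adjusted p = 9.52e-12, and adjusted p = 0.185 with an estimated correlation). Of 20 DNA replication genes 18 fell and 0 rose, or 20 and 0 adjusted over the list alone, with the helicase subunits MCM5 and MCM6 at -1.09 and -1.02 (adjusted p = 9.52e-12, and adjusted p = 0.185 with an estimated correlation). Of 17 genes of ribosome biogenesis 17 fell, also over the list alone, by a median of 0.80, with DDX21 at -1.18 and BOP1 at -1.05 (adjusted p = 5.76e-17, and adjusted p = 0.0714 with an estimated correlation). In all, 3810 genes passed the test after si-mut, 1783 higher and 2027 lower, and 308 of them changed at least 2-fold.

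Knockdown of both forms lowered Wnt targets. Of 18 members 13 fell and 1 rose, also over the list alone (adjusted p = 1.35e-08, and adjusted p = 0.123 with an estimated correlation). LGR5 fell 9.07-fold, NOTUM 8.26-fold and AXIN2 8.12-fold, and CEMIP fell to a level of 5.16 (log2 changes -3.18 ± 0.43, -3.05 ± 0.23, -3.02 ± 0.26 and -3.65 ± 0.24, SE, n = 3 arrays per group, limma adjusted p = 5.87e-05, 3.99e-07, 1.21e-06 and 8.82e-08). GSTA2 rose 36.9-fold, KNG1 27.1-fold, FETUB 25.5-fold, GSTA1 24.6-fold and SNAI2 19.3-fold. KNG1 rose by 2.45 on the log2 scale with the mean of its probe sets. DKK4 rose 12.3-fold. From siCtrl levels of 4.99 and 4.70, close to the array floor, HABP2 rose by 5.48 on the log2 scale and DPYD, which degrades pyrimidines, by 3.98. PGC, CHST15, NKD1 and IGFBP1 were the other genes among the 8 largest decreases, at -2.97, -2.89, -2.88 and -2.73. The first si-both array stood apart on some Wnt targets, with LGR5 at 9.10 beside 7.79 and 7.79 and NKD1 at 8.27 beside 6.96 and 7.35. In all, 5000 genes passed the test, 2309 higher and 2691 lower, and 584 of them changed at least 2-fold.

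After si-both, 23 of 26 secreted plasma proteins rose and 1 fell, or 23 and 2 adjusted over the list alone, with HPX at 3.18 (adjusted p = 8.63e-13, and adjusted p = 0.116 with an estimated correlation). Periportal genes rose in 6 of 10 cases and fell in 1, also over the list alone, with HAL at 2.44 (adjusted p = 0.00788, and adjusted p = 0.116 with an estimated correlation). Genes on the cholesterol synthesis list rose in 12 of 17 cases and fell in 0, also over the list alone, with the sterol transfer gene STARD4 at 0.57 and SQLE at 0.31 (adjusted p = 1.21e-05, and adjusted p = 0.159 with an estimated correlation). Fatty acid oxidation genes rose in 5 of 10 cases and fell in 0, or 6 and 1 adjusted over the list alone, with CPT1A at 1.85 (adjusted p = 0.000125, and adjusted p = 0.118 with an estimated correlation). Acute phase genes rose in 8 of 14 cases and fell in 1, also over the list alone, with the chemokine CXCL8 at 2.59 and HAMP at 1.75 (adjusted p = 0.00192, and adjusted p = 0.116 with an estimated correlation). The p53 targets rose in 9 of 16 cases and fell in 3, or 11 and 4 adjusted over the list alone, with TP53INP1 at 1.70, SESN2 at 1.61 and GDF15 at -0.50 (adjusted p = 0.00548, and adjusted p = 0.116 with an estimated correlation). Bile acid genes rose in 3 of 4 cases, also over the list alone (adjusted p = 0.0107, and adjusted p = 0.116 with an estimated correlation). Of the 3 measured drug metabolism genes GSTA1 and GSTA2 rose, also over the list alone (adjusted p = 0.00272, and adjusted p = 0.116 with an estimated correlation). Mitosis genes fell in 18 of 19 cases, or 19 adjusted over the list alone, with BUB1 at -1.18 (adjusted p = 1.4e-11, and adjusted p = 0.152 with an estimated correlation). DNA replication genes fell in 20 of 20 cases, also over the list alone, with MCM3 at -1.78 (adjusted p = 1.98e-11, and adjusted p = 0.152 with an estimated correlation). Ribosome biogenesis genes fell in 16 of 17 cases, also over the list alone, with BOP1 at -1.59 (adjusted p = 2.32e-12, and adjusted p = 0.116 with an estimated correlation). Glycolysis and hypoxia genes fell in 12 of 15 cases, or 13 adjusted over the list alone, with the hexokinase HK2 at -2.29 and PGK1 at -1.08 (adjusted p = 2.3e-06, and adjusted p = 0.116 with an estimated correlation). The lists of hepatocyte transcription factors and lipogenesis, called after si-mut, were not called after si-both (adjusted p = 0.0888 and 0.224), and si-both against si-mut gave adjusted p = 0.909 and 0.085 for them.

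**Figure D2:**
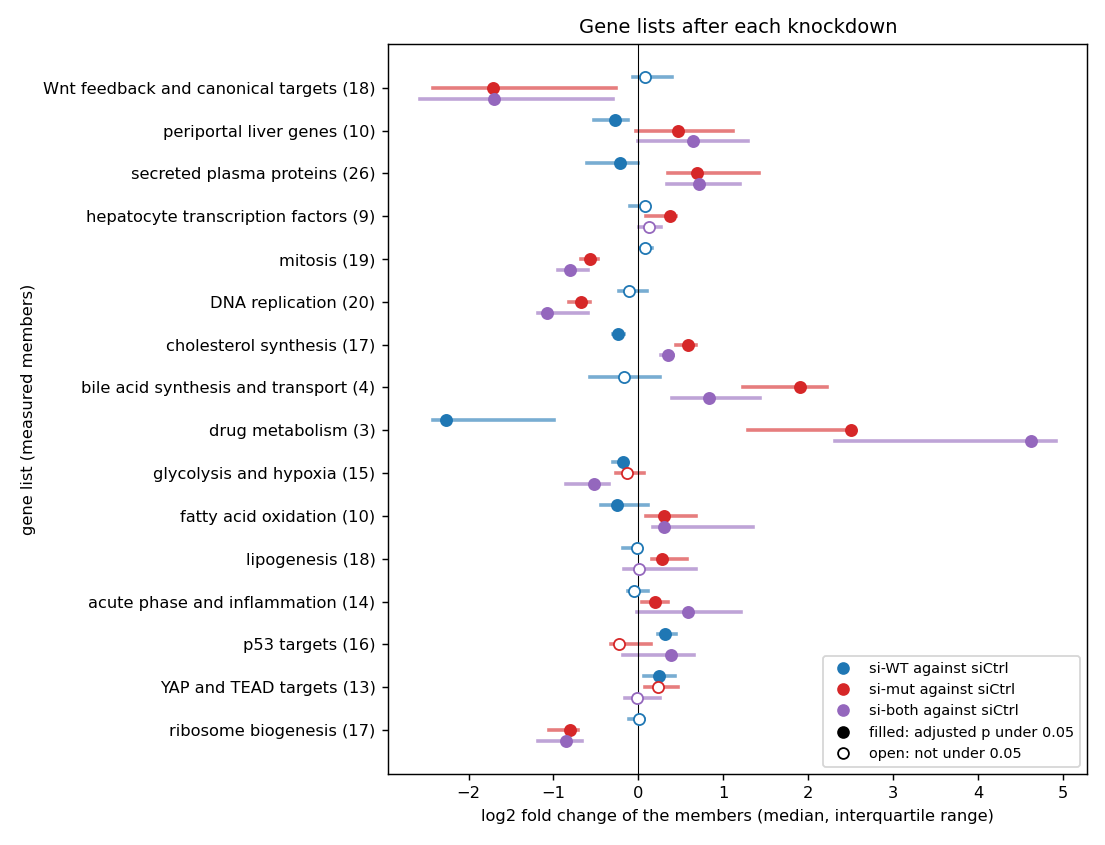
Median (points) and interquartile range (lines) of the log2 fold changes of the measured members of 16 gene lists, called in at least 1 of the 3 comparisons against siCtrl, with members counted in brackets. Filled points passed camera with a preset correlation; Wnt targets have a median of 0.08 after si-WT, -1.71 after si-mut and -1.70 after si-both.

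The other 11 lists were not called in any of the 3 comparisons against siCtrl. The interferon response list, which holds genes induced by foreign RNA, had adjusted p = 0.603, 0.0629 and 0.0705 after si-WT, si-mut and si-both, with XAF1 at 1.68 after si-both. In si-both against si-WT 9 of its 24 members were higher and 4 lower, or 12 and 4 adjusted over the list alone (adjusted p = 0.05, just inside the threshold, 0.0531 with the replicate number as a block, and adjusted p = 0.165 with an estimated correlation). This call ended without siCtrl replicate 2, si-WT replicates 1 and 3, si-both replicates 1 and 2, and si-mut replicate 3 (adjusted p = 0.0517, 0.0601, 0.0588, 0.0707, 0.0714 and 0.0502). It also ended with renewed quantile normalization (0.0617), median centring (0.0516) and array weights (0.0547), without dim genes (0.0825), and without the first arrays of si-mut and si-both (0.0674). Pericentral liver genes had adjusted p = 0.874, 0.423 and 0.516, but only 10 of the 24 listed were measured, so most of that list was not tested. Fetal and progenitor liver genes, with 18 of 22 measured, had adjusted p = 0.556, 0.698 and 0.835. SOX4 and CD24 of the fetal list rose by 1.34 and 1.47 after si-WT, and SOX9 fell by 1.55 after si-both. Genes of the actin cytoskeleton had adjusted p = 0.384, 0.682 and 0.181, mesenchymal transition 0.603, 0.125 and 0.642, and cell-cell junctions 0.527, 0.239 and 0.382. The junction proteins CLDN1 and JUP rose by 1.60 and 0.91 after si-mut, and JUP fell by 0.37 after si-WT. The list of the unfolded protein response and ATF4 targets had adjusted p = 0.771, 0.567 and 0.169. Markers of other cell types were not called against siCtrl: stromal cells 0.458, 0.626 and 0.841, endothelial cells 0.325, 0.27 and 0.749, leukocytes 0.325, 0.304 and 0.169, and cholangiocytes 0.603, 0.239 and 0.0754. The cholangiocyte list was called in si-both against si-mut, with 3 of 9 members lower and 0 higher (adjusted p = 0.0451, with 4 lower and 0 higher adjusted over the list alone, and adjusted p = 0.276 with an estimated correlation). That call ended without si-WT replicate 3, si-both replicates 1 and 3, and si-mut replicates 2 and 3 (adjusted p = 0.0505, 0.0597, 0.0514, 0.0654 and 0.0512), and with only the groups compared in the fit (0.0541).

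The direct comparison of the single knockdowns shows where loss of the truncated form and loss of the full-length form gave different levels. HAL, GSTA2, GSTA1 and HABP2 were higher after si-mut than after si-WT, by 5.19 ± 0.19, 5.17 ± 0.23, 4.77 ± 0.17 and 4.31 ± 0.19 on the log2 scale (SE, n = 3 arrays per group, limma adjusted p = 8.98e-10, 3.61e-09, 6.12e-10 and 3.01e-09). The levels of HAL, GSTA2 and HABP2 after si-WT, 4.90, 4.93 and 5.32, were close to the array floor. LGR5 was 21.9-fold lower, NKD1 15.8-fold and AXIN2 14.9-fold. The integrin ligand NPNT and FRMD5 had log2 differences of -3.05 and -3.00, with levels of 5.19 and 5.22 after si-mut. Without si-mut replicate 1 the log2 difference of LGR5 was -5.08. In all, 4611 genes differed, 2081 higher after si-mut and 2530 lower. Of 26 secreted plasma proteins 25 were higher and 0 lower, also over the list alone (adjusted p = 2.31e-22, and adjusted p = 0.0495 with an estimated correlation). Of 10 periportal genes 6 were higher and 0 lower, and of 16 p53 targets 1 was higher and 12 lower, with the same counts over the list alone (adjusted p = 6.59e-05 and 2.35e-05, both adjusted p = 0.0495 with an estimated correlation). These were the 3 of 14 called lists whose call held with an estimated correlation. The other 11 were Wnt targets, hepatocyte transcription factors, mitosis, DNA replication, cholesterol synthesis, bile acid genes, drug metabolism, fatty acid oxidation, lipogenesis, acute phase and ribosome biogenesis, with adjusted p = 0.0529 to 0.261 with an estimated correlation. Against siCtrl, 0 of the 8, 13 and 13 lists called after si-WT, si-mut and si-both held in camera with an estimated correlation. There 4, 8 and 10 lists had an unadjusted p under 0.05, and fry called 13, 23 and 23.

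Of the 789 genes called in both single knockdowns against siCtrl, 272 fell after si-WT and rose after si-mut and 155 rose after si-WT and fell after si-mut, 427 in all, while 204 rose in both and 158 fell in both, 362 in all. Independent lists of these sizes would share 88.5, 105, 92.7 and 101 genes. GSTA2, GSTA1, PLG, PLGLA, UNC93A, the antimicrobial peptide LEAP2, the lipid droplet gene CIDEC and EPO (erythropoietin) fell after si-WT and rose after si-mut, for example LEAP2 by -1.31 and 1.63 and EPO by -1.11 and 1.33. The matrix protein THBS1 rose by 1.18 after si-WT and fell by 1.44 after si-mut, and LRRN4 rose by 1.12 and fell by 1.46. Across all genes the log2 changes of the 2 comparisons correlated at r = -0.029, against 0.499 for simulated unchanged groups sharing the same controls, a value that holds only where all variation is noise. Their covariance was -0.0024 beside a simulated 0.0059, a difference of -0.0083. The 3 controls cannot be split into parts of at least 2, so the observed values carry their shared error. The count of 427 was 279, 254 and 264 without siCtrl replicates 1, 2 and 3.

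**Figure D3:**
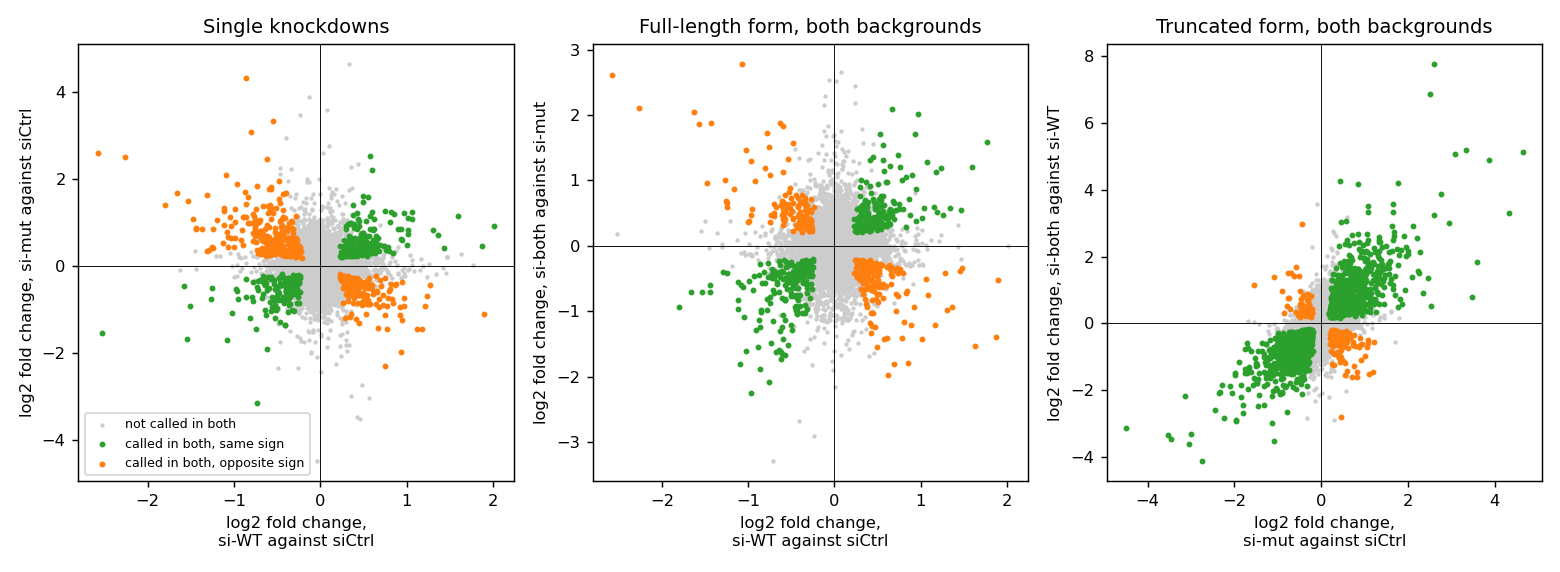
Log2 fold changes of 14884 genes in pairs of comparisons: si-WT against si-mut effects over siCtrl (left), the si-WT effect against si-both over si-mut (middle), and the si-mut effect against si-both over si-WT (right). Green points were called in both comparisons with the same sign, orange points with opposite signs (427 on the left), and grey points were not called in both; r is -0.029, 0.043 and 0.65 from left to right.

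The same forms were also removed together, which gives a second estimate of each effect from other arrays, but with a separate RNA, so that differences between the RNAs are part of it. Each estimate holds only if si-both lowered a form as far as the single RNA did, which could not be checked here. The effect of removing the truncated form in cells that also lost the full-length form, si-both against si-WT, took in 5383 genes, 2397 higher and 2986 lower. GSTA2 was higher by 7.78, GSTA1 by 6.88, FETUB by 5.21 and HABP2 by 5.15, and CEMIP was lower at -4.13, NOTUM at -3.61, FRMD5 at -3.52 and AXIN2 at -3.45. This effect correlated with that of si-mut against siCtrl across genes at r = 0.65, and 84.6% of the 3810 genes called there had the same sign. Of the 2696 genes called in both, 2488 had the same sign and 208 opposite signs. The effect of removing the full-length form in cells that also lost the truncated form, read from si-both against si-mut, took in 3297 genes, 1575 higher and 1722 lower. Of 18 Wnt targets 3 were higher and 0 lower, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.205). In this list DKK4, which rose after si-mut, stood higher still after si-both (11.34, 11.34 and 11.09 beside 9.61, 9.57 and 9.07). The count of higher members therefore does not show whether the truncated form was lost unequally. Part of the 3297 genes may still reflect unequal loss of it, which was not tested. IGFBP1 was lower at -3.30, VNN1 at -2.91, the immediate early gene EGR1 at -2.68 and TINAG at -2.26, and AADAC, a liver deacetylase, was higher by 2.78, OSBPL6 by 2.67, GSTA2 by 2.61 and the metallothionein MT1B by 2.54. With the mean of its probe sets EGR1 was at -1.78. Of 16 p53 targets 10 were higher after si-both than after si-mut and 2 lower, or 11 and 2 adjusted over the list alone (adjusted p = 1.21e-06, and adjusted p = 0.0576 with an estimated correlation). Of 19 mitosis genes 7 were lower and 0 higher, or 8 and 0 adjusted over the list alone (adjusted p = 0.0106, 0.125 without si-both replicate 3, adjusted p = 0.775 with an estimated correlation, and 0.073 with fry). Of 20 DNA replication genes 7 were lower and 2 higher, or 8 and 3 adjusted over the list alone (adjusted p = 0.0496, and adjusted p = 0.849 with an estimated correlation). The DNA replication call ended without siCtrl replicates 1, 2 and 3 (adjusted p = 0.0551, 0.0546 and 0.0555), si-WT replicates 1, 2 and 3 (0.051, 0.0581 and 0.0535), si-both replicates 2 and 3 (0.294 and 0.125) and si-mut replicates 1 and 2 (0.0755 and 0.0868). It also ended with only the groups compared in the fit (0.0671), without dim genes (0.13) and with fry (0.199). Of 15 genes of glycolysis and hypoxia 9 were lower and 0 higher, or 14 and 0 adjusted over the list alone (adjusted p = 9.2e-07, and adjusted p = 0.251 with an estimated correlation). Of 17 genes of cholesterol synthesis 6 were lower and 0 higher, also over the list alone (adjusted p = 0.0224, 0.11 without si-both replicate 3, and adjusted p = 0.644 with an estimated correlation). Fatty acid oxidation genes were higher in 5 of 10 cases and lower in 0, also over the list alone, and drug metabolism genes in 2 of 3 cases (both adjusted p = 0.0106, and adjusted p = 0.445 and 0.283 with an estimated correlation). The effect of si-both against si-mut correlated with that of si-WT against siCtrl at r = 0.043. Of the 1513 genes called after si-WT 52.3% had the same sign, beside 51.4% over all genes and 50% in simulated unchanged groups. Of the 689 genes called in both, 387 had the same sign and 302 opposite signs. Genes are not independent replicates, and these correlations across genes describe these arrays.

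The single effects did not add up to the effect of si-both for 2439 genes, of which 1131 stood higher than the sum and 1308 lower. AXL and ESAM, which rose after si-WT, were lower than siCtrl after si-both (log2 changes -0.92 ± 0.14 and -1.25 ± 0.18, SE, n = 3 arrays per group, limma adjusted p = 0.000176 and 0.000103). GSTA2 stood at 7.51 ± 0.06 after siCtrl, 4.93 ± 0.67 after si-WT, 10.10 ± 0.19 after si-mut and 12.71 ± 0.07 after si-both (SD, n = 3). CES1 stood at 8.60 ± 0.05, 6.97 ± 0.27, 8.49 ± 0.25 and 10.54 ± 0.23 in the same order, and AADAC at 4.98 ± 0.15, 3.91 ± 0.11, 5.41 ± 0.10 and 8.20 ± 0.33. VNN1 stood at 4.18 ± 0.14, 3.95 ± 0.27, 7.66 ± 0.49 and 4.76 ± 0.30. GSTA2 after si-WT, AADAC after siCtrl and si-WT, and VNN1 after siCtrl, si-WT and si-both lay near the array floor. A decrease is compressed there, so the size of their departures is uncertain. Of 13 YAP and TEAD targets 6 stood lower than the sum and 1 higher, also over the list alone (adjusted p = 0.000983, and adjusted p = 0.281 with an estimated correlation). Of 19 mitosis genes 6 stood lower and 0 higher, also over the list alone (adjusted p = 0.00219, adjusted p = 0.512 with an estimated correlation, and 0.0717 with fry). Of 15 genes of glycolysis and hypoxia 4 stood lower and 0 higher, or 5 and 1 adjusted over the list alone (adjusted p = 0.0289, and adjusted p = 0.486 with an estimated correlation). Higher than the sum stood 5 of 10 genes of fatty acid oxidation, with 0 lower, and 2 of 3 drug metabolism genes, with 0 lower, both also over the list alone (adjusted p = 0.000659 and 0.00219, both adjusted p = 0.281 with an estimated correlation). Of 26 secreted plasma proteins 11 stood higher and 3 lower, or 13 and 3 adjusted over the list alone (adjusted p = 0.00219, and adjusted p = 0.486 with an estimated correlation). Of 14 acute phase genes 6 stood higher and 1 lower, or 6 and 2 adjusted over the list alone (adjusted p = 0.00947, 0.103 without dim genes, and adjusted p = 0.281 with an estimated correlation). Of 16 p53 targets 9 stood higher and 3 lower, or 10 and 3 adjusted over the list alone (adjusted p = 0.0495, and adjusted p = 0.362 with an estimated correlation). The p53 call ended without siCtrl replicate 3, si-WT replicate 1, si-both replicates 2 and 3, and si-mut replicates 1 and 2 (adjusted p = 0.0827, 0.0992, 0.0853, 0.0586, 0.0944 and 0.0613), with renewed quantile normalization (0.0669), median centring (0.0727) and without dim genes (0.181). The glycolysis call ended without siCtrl replicate 3, si-WT replicate 3, si-both replicates 1 and 2, and si-mut replicate 1 (adjusted p = 0.068, 0.0551, 0.0513, 0.0613 and 0.0806), without the first arrays of si-mut and si-both (0.11) and without dim genes (0.0926). Against siCtrl, the effects of si-mut and si-both correlated at r = 0.713 (simulated 0.499, covariance 0.113 beside 0.0059, a difference of 0.107), and 2568 of 2707 genes called in both had the same sign. Independent lists would share 277 genes higher in both, where 1092 were found, and 366 lower in both, where 1476 were found. The effects of si-WT and si-both correlated at r = 0.007 (simulated 0.5, covariance 0.0007 beside 0.0059, a difference of -0.0052), with 470 genes of the same sign and 465 of opposite signs. Part of any excess in these comparisons may come from the shared controls.

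**Figure D4:**
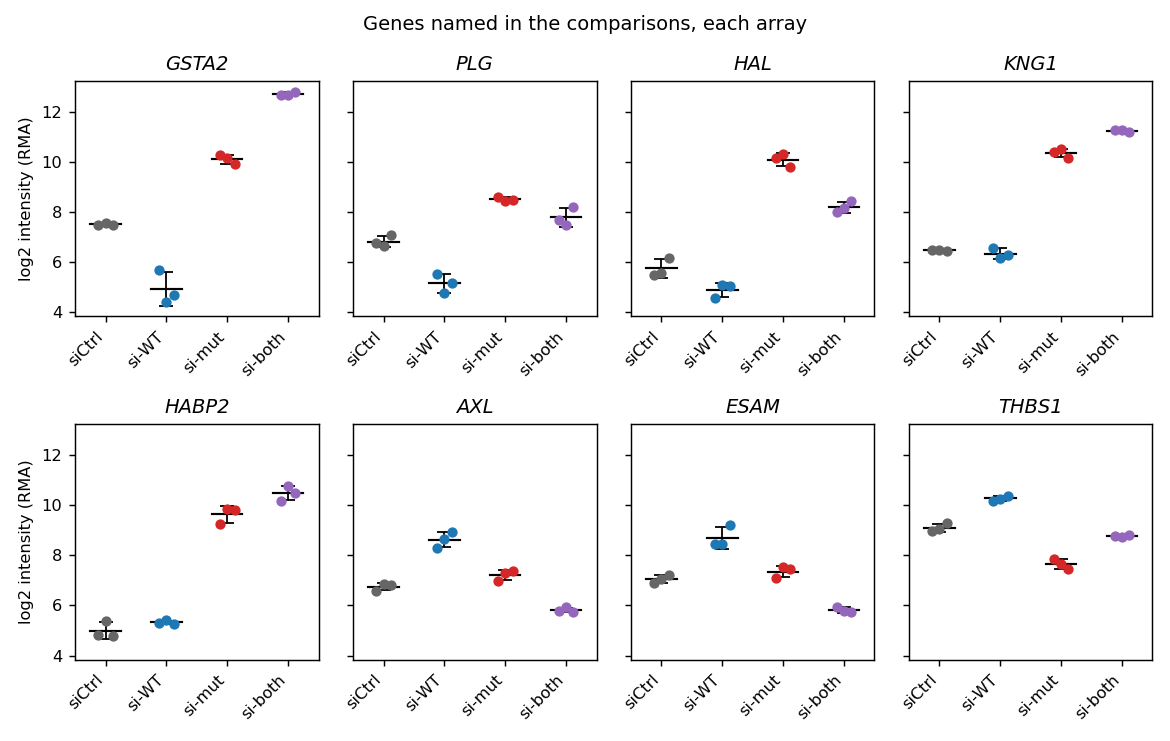
Log2 intensity (RMA, vertical axis) of 8 genes in the 4 groups, where points are single arrays in replicate order and bars are the mean and SD of 3 arrays. GSTA2 is lowest after si-WT and highest after si-both, AXL and ESAM are highest after si-WT and lowest after si-both, and THBS1 is highest after si-WT and lowest after si-mut.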

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

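Of the tests in this part, those of noise hiding equal effects, of shared control arrays and of reordered residuals were chosen after the results were seen.

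The effect of si-both differed from the sum of the effects of si-WT and si-mut by the interaction contrast in limma (3 arrays in each of the 4 groups); si-both is a separate RNA, so the contrast also holds differences between the RNAs. AXL departed from the sum of the single effects by -3.26 on the log2 scale, ESAM by -3.17, VNN1 by -2.67 and PAEP by -2.65. GSTA2 departed by 5.19, GSTA1 by 4.38, AADAC by 3.85 and CES1 by 3.67 (2.92 with the mean of its probe sets). GSTA2 after si-WT, AADAC after siCtrl and si-WT, VNN1 after siCtrl, si-WT and si-both, and PAEP after siCtrl and si-both lay near the array floor, so the size of their departures is uncertain. In all 2439 genes departed. Splits of the 12 arrays also break the single effects, so they do not bear on additivity (1 of 100 reached the count, the real split, and the highest other gave 268). With the single effects kept, the residuals of the additive fit were reordered over the arrays. Of 100 orders 1, the real one, reached the count and the highest other gave 140, which argues against a random arrangement of these arrays. The orders ignored the replicate numbers and treated the arrays as separate samples. They cannot exclude chance differences between cultures. Among the 37519 probe sets without a gene name, which no comparison used, 839 were called after si-WT, 3672 after si-mut and 5705 after si-both (2.2%, 9.8% and 15.2%).

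Of the 1513 genes called after si-WT, 52.3% kept their sign in si-both against si-mut. Over all genes this share was 51.4%, and in simulated unchanged groups 50%, so across genes the effects of si-WT were repeated little. With a preset correlation p53 targets, glycolysis and cholesterol synthesis were called in the same direction in both comparisons (camera adjusted p = 0.0538 to 0.644 with an estimated correlation). Without si-both replicate 3 cholesterol synthesis had 0.11 at the preset correlation. Fatty acid oxidation and drug metabolism were called in opposite directions (adjusted p = 0.496 and 0.445, and 0.165 and 0.283, with an estimated correlation). Fatty acid oxidation after si-WT had 0.0501 without si-WT replicate 3. Secreted plasma proteins, periportal genes and YAP and TEAD targets were called after si-WT but not in si-both against si-mut (adjusted p = 0.909, 0.735 and 0.088). Noise alone hiding equal effects is argued against by the genes called in both comparisons, of which 56.2% kept their sign where equal effects would give nearly all. A floor or ceiling of the array is argued against by the 1094 genes with all group means between 6 and 11, where the share was 53.1%. Off-target transcripts of a reagent may add to the difference and cannot be told apart from it here, since 48.8% of the called genes were lower after si-WT and indirect effects go both ways. How far si-both and si-mut each lowered the truncated form could not be checked here. That part of what the full-length form does differs where the truncated form is present stays open as a hypothesis.

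Genes called after si-WT and after si-mut moved in the same direction in 362 cases, not far fewer than those that moved in opposite directions, 427. Splits of the 9 arrays break both effects at once, so they do not bear on how the directions combine (1 of 100 reached the count, the real split, and the highest other gave 1, or 83 over all 839 other splits). Shared controls push both comparisons towards the same sign, so they would not produce opposite directions. The covariance of -0.0024 (up to 6e-04 with each array left out in turn) lay below the lowest of simulated unchanged groups, 0.0055. That result lends no support to any cause of the opposite directions. Of the 589 genes with all group means between 6 and 11, 53.1% went in opposite directions. A floor or ceiling compresses changes and would not reverse their sign, so this share does not bear on the cause of the opposite directions. A biological explanation, that the forms act against each other on these genes, is consistent with these values but remains a hypothesis, since off-target effects of the reagents were not excluded.

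The first arrays of si-mut and si-both held higher levels of some Wnt targets, among them LGR5 and NKD1, than the other arrays of their groups. A weaker effect in all cells of those samples is argued against by the strongly raised genes, whose log2 change in the first array was 1.008 of that in the others for si-mut and 0.944 for si-both. RNA from cells that the knockdown did not reach may explain part of the si-both array. There lowered genes outside the Wnt list held a median of 9.6% of the control level above the other arrays (bootstrap interval over genes of this array 5.04 to 16.0), beside 13.1% in the Wnt list. Over all 27 lowered genes the interquartile range was 6.76% to 15.6%. Such RNA would raise every strongly lowered gene. But CHST15 (6.98 beside 7.01 and 7.35) and IGFBP1 (7.40 beside 7.79 and 8.69) were not higher in the first array, so this explanation stays open. For the si-mut array the share outside the Wnt list was 4.68% (-0.13 to 12.1), beside 7.1% in the Wnt list, and too few lowered genes keep it open. No biological explanation was tested for single arrays.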

How the results depend on the processing

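The alternative that leaves out the first arrays of si-mut and si-both was chosen after seeing the data; the others were planned. No called list median and no named gene that was called changed direction under the alternatives run; the lists were not run with the trended and robust priors. With at least a 1.5-fold change the counts fell to 380 (si-WT against siCtrl), 1176 (si-mut), 1849 (si-both), 1600 (si-mut against si-WT), 2176 (si-both against si-WT), 858 (si-both against si-mut), 1237 (additivity), 2384 (among the 4 groups) and 101 (opposite directions), because fewer genes can pass. At an adjusted p under 0.01 they were 750 for si-WT, 2028 for si-both against si-mut, 1288 for additivity and 203 for opposite directions. Lists called by camera after si-WT, si-mut and si-both, in si-mut against si-WT, in si-both against si-WT and si-mut, and for additivity numbered 8, 13, 13, 14, 13, 8 and 8. With an estimated correlation they were 0, 0, 0, 3, 0, 0 and 0 (4, 8, 10, 10, 8, 4 and 4 at an unadjusted p under 0.05), and with fry, which does not compare a list with other genes, 13, 23, 23, 22, 25, 15 and 14. At an adjusted p under 0.01 the lists in si-both against si-mut were 2, and without dim genes those for additivity were 5. With each array left out in turn, the counts ranged from 917 to 1616 for si-WT, 3094 to 3930 for si-mut, 4364 to 4998 for si-both, 3983 to 4754 for si-mut against si-WT, 4820 to 5387 for si-both against si-WT, 2590 to 3371 for si-both against si-mut, 1912 to 2589 for additivity, 6332 to 6731 among the 4 groups and 254 to 464 for opposite directions. The si-WT count was 950 without siCtrl replicate 2, 917 without si-WT replicate 2 and 957 without si-WT replicate 3, and the opposite count was 279, 254 and 264 without siCtrl replicates 1, 2 and 3. Lists called then ranged from 7 to 9, 13 to 14, 13 to 14, 14 to 14, 12 to 14, 4 to 9 and 6 to 8, with the 4 without si-both replicate 3. With the replicate number as a block the counts were 1669, 4024, 5206, 4791, 5623, 3523, 2607, 7002 and 481, in the order of the first counts given, and 8, 14, 13, 14, 12, 8 and 8 lists. Outside si-both against si-WT the rule for pairing was not met. Yet 11 of 12 arrays correlated best with their own number, and the block raised each of these counts of genes. Together these values point to a replicate effect across the groups, small in the paired correlations (-0.047 to 0.189). The main counts were made without the block, also for si-both against si-WT, and the block moved no count by over 1.5 times. For si-both against si-WT, where the numbers pair the arrays, the block ended the call of the interferon list (adjusted p = 0.0531) and changed the call of no other list and no named gene. Without the first arrays of si-mut and si-both the counts were 1564, 3489, 4853, 4280, 5225, 2898, 2339, 6425 and 408. Among named genes, 110 results lost and 6 gained their call with an array left out, against 5392 that did not change; under the other alternatives 136 lost and 16 gained it. Where the cause of a moved value is not in the alternative's construction, the cause was not tested. Splits of 6 arrays number 10, too few for a share under 0.05; the real split (1 of 10) gave 1513, 3810, 5000, 4611, 5383 and 3297 genes and the highest other 0 in each comparison, also among splits of si-both and si-WT that part all 3 pairs. For the 4 groups, the real split gave 6749 genes, the highest of the other splits 1478, and 1 of 100 reached the real count. This argues against a random arrangement of these arrays. Since the samples may be technical replicates, it cannot exclude chance differences between cultures. Signal over background limits dim genes, for which the array floor compresses changes.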

Other observations

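The tests in this part were chosen after the results were seen, on gene lists written for them, and the genes named in it were chosen after their values were seen. A list of genes induced by ERK signalling, only some of which feed back on it, was lower after si-both. Of 11 measured members 8 fell and 0 rose against siCtrl, by a median of 0.97 on the log2 scale, and 8 fell and 0 rose against si-mut, by a median of 0.94. ETV1, DUSP4 and DUSP5 did not pass the test against siCtrl (limma adjusted p = 0.811, 0.367 and 0.414). The transcription factor ETV4 fell by 2.01 against siCtrl, IER3 by 2.14, SPRY4 by 1.68, the phosphatase DUSP6 by 1.21 and ETV5 by 0.89. After si-mut 3 of these genes rose and 3 fell, with EGR1 at 1.71 and FOSL1 at -0.91, and after si-WT 3 rose, with DUSP5 at 1.37, FOSL1 at 0.97 and IER3 at 0.69. A candidate explanation is lower ERK signalling when both forms are lost; the genes moved together against si-mut (camera p = 5.93e-08, and p = 0.0157 with an estimated correlation), but EGR1 was among the genes that led to the list, so this remains a hypothesis.

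Metallothionein genes, which bind zinc and copper, were higher after si-both. Of 8 measured members 8 rose against siCtrl, with MT1B at 3.14, MT1M at 2.57 and MT1F at 1.15 (camera p = 1.69e-07, and p = 0.0354 with an estimated correlation). After si-mut 6 rose and 0 fell, and after si-WT MT1F fell by 0.81 and no other member passed the test. Against si-mut 2 rose and 0 fell (camera p = 0.00104, and p = 0.152 with an estimated correlation), so a difference between si-both and si-mut is consistent with these values only at the preset correlation. The metallothionein genes are near-identical copies that can share probe signal, MT1B and MT1H lie near the array floor after siCtrl (3.56 ± 0.13 and 3.77 ± 0.17, SD, n = 3), and MT1B led to the choice of the list.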
